A study of Cavia porcellus with 8 samples.

How the data were processed

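RNA of the left ventricular wall of guinea pigs (Cavia porcellus, Dunkin Hartley strain) was sequenced from 4 adult, non-pregnant animals and 4 foetuses of gestation day 67. Per the labels' protocols, hearts were flushed through the aorta with a cardioplegic solution, a cold potassium-rich fluid that stops the heart, to remove blood. Total RNA was then extracted from frozen tissue. Libraries were made with a strand-specific total RNA kit that depletes ribosomal RNA, and were read on an Illumina HiSeq instrument, per the labels. The labels call the libraries of each group biological replicates. The litter and the sex of each foetus are not given in the sources used here. The sex of the adults is not stated as such, but the label non-pregnant implies that they were female. If the foetuses were not all female, a difference in sex between the groups cannot be told apart from age. Foetus replicates 1 and 2 have descriptions that open with the same number, whose meaning is not given either.

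The deposited count files, 1 per library, held whole-number counts of reads for 25028 Ensembl guinea pig gene IDs, with no normalization. Below the genes each file had 5 summary lines that name no gene, with the names that the program htseq-count writes. The program that counted, its strand setting, the aligner, the genome build and the annotation are not given in the sources used here. The authors also deposited a table of normalised counts, a signal in which the counts of each library had been divided by 1 size factor. DESeq2 is named for the data, without a version, per the submitters' processing notes. The size factors implied by the deposited table ran from 0.862 to 1.24 and were equal to those computed here with DESeq2 from the counts. No column belonged to any other sample.

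The summary lines stayed out of library sizes and tests. Of the reads in each file, 30.5% to 38.8% were assigned to a gene, 24.6% to 31.6% overlapped no annotated feature, 33.9% to 38.1% had no unique position, and 0.0201% to 0.0536% were ambiguous between genes. Reads with no unique position had been assigned to no gene, so the counts of genes with near-identical copies are uncertain. Because the strand setting is not given, overlapping and antisense genes are uncertain as well. Counts assigned to genes ran from 8009143 in Adult replicate 4 to 10846059 in Adult replicate 3. A gene with 0 counts in a library could have had up to 3 counts by chance, which is 0.255 to 0.371 CPM (counts scaled to a common library total, as cpm in edgeR gives them) depending on the library. These limits and the 95% Wilson intervals of shares cover counting error only.

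The files do not pair the IDs with gene names. A reference table of 37416 genes was searched, and 0 IDs matched. The 34 gene lists and 18 isoform pairs fixed for testing, the set tests on them, and the shares of mitochondrial, erythroid and ribosomal genes all needed gene names and were not analysed here.

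Counts were tested with the quasi-likelihood test of edgeR (version 4.0.16 in R 4.3.3) with a robust fit, adult against foetus, with no covariate. Library sizes were scaled by TMM, and genes with low counts were removed with filterByExpr, which left 11831 of the 17077 IDs with any count. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The SE of a log2 fold change was its size divided by the square root of the F statistic of the test, which makes it approximate. A doubling or halving means a called gene with a log2 fold change of at least 1 in size. CPM values used the TMM-scaled library sizes, except that the number of genes at 1 CPM in a library used its total without that factor. Distances, principal components and spreads used log2 CPM with a prior count of 2. The spread of a group was the root mean square over genes of the SD between its libraries. Its permutation test compared the ratio of both spreads over the 35 splits of the 8 libraries after each group was centred on its mean, two-sided, which makes it approximate. Measures of single libraries were compared by two-sided exact permutation tests over 70 assignments, with a smallest possible p of 0.0286, adjusted over 6 measures. In groups of 4, a library was singled out where its gap to the nearest of the others, relative to the range of the group, exceeded Dixon's 95% critical value.

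The comparison, the test, its thresholds, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, in each direction, the called gene with the largest fold change, among genes with at least 5 CPM in the higher group and no overlap between the groups, and the called gene with the largest difference in mean CPM. It was written for more genes, all with a gene symbol. That condition was dropped because there were no symbols, and 2 higher and 2 lower IDs are printed. ENSCPOG00000017401 falls outside the rule and was chosen after its values were seen. The breakdown by abundance, the comparison of spreads, the tests of Adult replicate 4, the measures of library make-up other than the share of the 10 most abundant genes, and the alternatives that thinned or weighted libraries or left out abundant genes were added after the data were examined.

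Alternatives included other scalings, filters and thresholds, the DESeq2 (version 1.42.0) Wald test, limma-voom (limma version 3.58.1), each library left out in turn, the replicate number as a block, and Foetus replicates 1 and 2 summed. The pipeline was tested on simulated counts for the 11831 genes, with 200 genes changed in each simulation. In the first simulation 16 of 145 calls were false, or 11.0%, above the limit of 10% set for this test. After that result 3 more simulations were run, and over all 4 simulations 34 of 546 calls, or 6.23%, were false. Pooled over the 4, the test recovered 23.5% of genes changed 1.5-fold, 72.4% of those changed 2-fold and 96.6% of those changed 4-fold. The p-value that passes the adjusted threshold depends on how many genes change. The rates of recovery and of false calls may therefore not carry over to the data, where 4032 genes were called. The spread ratio was 0.995 in counts simulated with equal spread and 1.85 where the adult libraries were given an extra log2 SD of 0.5.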

Results

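The series compared the transcriptome of the guinea pig left ventricle just before birth with that of the adult. Total RNA was profiled in 4 adult and 4 foetal hearts, the foetuses at gestation day 67, which is term in this species. The adult libraries held 8942220, 10154038, 10846059 and 8009143 counts assigned to genes for replicates 1 to 4. The foetal libraries held 9322073, 9918161, 9100101 and 9977233. At these depths 17077 of 25028 annotated genes had at least 1 count in some library, and 11831 passed the filter on low counts and were tested. Genes are given by Ensembl ID, since the files do not pair IDs with names.

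Expression differed between adult and foetal ventricle in 4032 of the 11831 genes tested, or 34.1% (adjusted p under 0.05, quasi-likelihood test of edgeR). Of these, 2175 were higher in the adult and 1857 were lower. ENSCPOG00000008709 rose from near the detection limit in the foetus, at 0.807 ± 0.572 CPM (SD, n = 4), to 55.5 ± 30.4 CPM in the adult (n = 4). ENSCPOG00000026774 fell from 728 ± 83.5 CPM in the foetus to 13.5 ± 7.32 CPM in the adult (SD, n = 4 each). Among the most abundant transcripts, ENSCPOG00000016614 fell from 54016 ± 17409 CPM to 12979 ± 2990 CPM (SD, n = 4 each).

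ENSCPOG00000008709 had the largest rise among genes with at least 5 CPM in the higher group and no overlap between the groups, at 68.1-fold (log2 fold change 6.09, SE 0.58, adjusted p = 3.98e-05 by edgeR). The foetal value rested on 11, 8, 0 and 11 counts in replicates 1 to 4, and the count of 0 allows up to 0.324 CPM in Foetus replicate 3. The adult libraries ranged from 24.6 to 82.5 CPM. ENSCPOG00000026774 had the largest fall by the same rule, at 53.5-fold (log2 fold change −5.74, SE 0.43, adjusted p = 1.26e-05 by edgeR). Its foetal libraries lay between 654 and 848 CPM and its adult libraries between 2.72 and 18.7 CPM.

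ENSCPOG00000016614 showed the largest fall in absolute level, 4.16-fold (log2 fold change −2.06, SE 0.25, adjusted p = 0.000168 by edgeR). It made up 3.11% to 6.71% of all gene counts in the foetal libraries and 1.01% to 1.57% in the adult ones. Of the foetal libraries, replicate 3 had the lowest value, 30554 CPM, which was still above the highest adult value of 15958 CPM. ENSCPOG00000003907 showed the largest rise in absolute level. It was among the most abundant transcripts in both groups, at 105341 ± 17924 CPM in the adult and 71594 ± 19755 CPM in the foetus (SD, n = 4 each). This 1.47-fold difference (log2 fold change 0.56, SE 0.19) was close to the threshold, with an adjusted p of 0.0463 by edgeR. The ranges overlapped, since Foetus replicate 3 had 98719 CPM and Adult replicate 4 had 82139 CPM. The call was lost in 10 of the 21 alternative settings that tested it, over which the adjusted p ran from 0.0059 to 0.136. Leaving out any of Adult replicates 1, 2 and 3 or Foetus replicates 1, 2 and 4 ended it, with adjusted p of 0.0967, 0.106, 0.0833, 0.115, 0.136 and 0.109 in that order (edgeR).

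**Figure D1:**
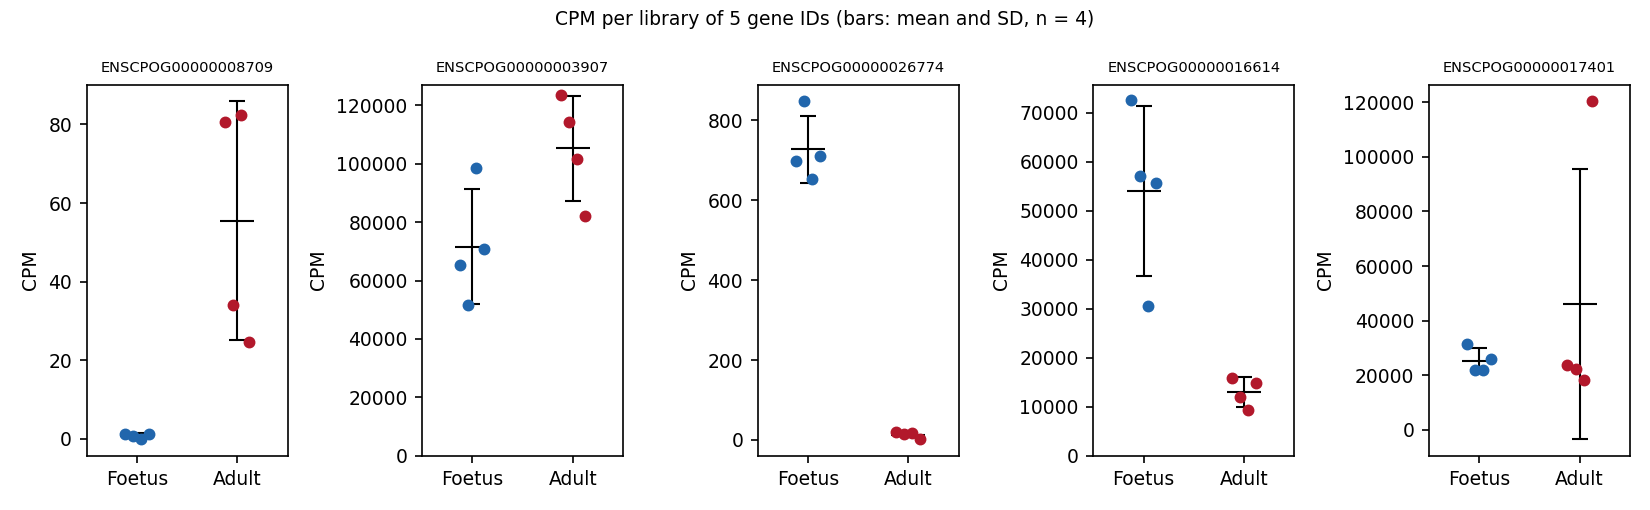
Expression of 5 genes in each library, in CPM on a linear axis for each gene. Points are libraries, and bars show the mean and SD of 4 libraries per group. ENSCPOG00000008709 was higher in the adult, and ENSCPOG00000026774 and ENSCPOG00000016614 were lower, with no overlap between the groups. In ENSCPOG00000017401 a single adult library lay at 120306 CPM.

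Most differences were moderate in size. The median change of the called genes was 0.70 on the log2 scale, and 2945 of them, or 73.0%, changed less than 2-fold. The adult level was at least doubled in 639 genes and at least halved in 448, so 58.8% of the 1087 genes changed at least 2-fold were higher in the adult. The excess was larger among larger changes. At least 4-fold changes were found in 152 genes higher and 78 lower in the adult, at least 8-fold changes in 61 and 18, and at least 16-fold changes in 30 and 6. The counts at these higher folds were taken in the main setting only. Whether they depend on scaling, on single libraries or on genes near the detection limit was not examined. In 3438 of the called genes, or 85.3%, the 4 adult values did not overlap the 4 foetal ones. Over all tested genes this held for 3927, or 33.2%, where chance gives 2.86%. Counts of at least 3 in each adult library and 0 in every foetal library were found for 13 genes, and the reverse for 4.

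**Figure D2:**
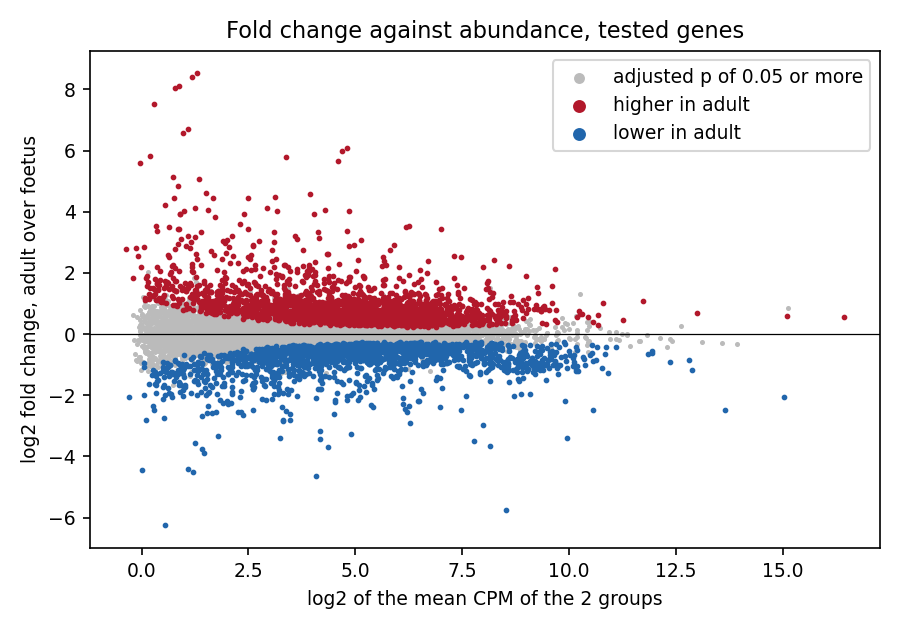
Log2 fold change of adult over foetus against the log2 of the mean CPM of both groups, 1 point per tested gene. Red points are the 2175 genes higher in the adult, blue points the 1857 genes lower, and grey points did not pass an adjusted p of 0.05 in edgeR.

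The counts of doubled and halved genes were set out by abundance, and differences between the abundance classes were not tested. Between 1 and 10 CPM, 308 genes were at least doubled and 213 at least halved in the adult, and between 10 and 100 CPM the counts were 265 and 137. Among the 1355 genes with a mean of 100 CPM or more, 60 were at least doubled and 97 at least halved, although scaling by library size alone turned this order, with 75 doubled and 69 halved. These abundant genes were called most often, with 745 of 1355 past the threshold, against 907 of 3792 genes between 1 and 10 CPM. The test has more power at higher counts, so shares called at different abundances do not compare the frequency of change. Over all called genes, library-size scaling gave 2515 higher and 1434 lower genes, while upper-quartile scaling turned the order, with 1958 higher and 2038 lower.

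**Figure D3:**
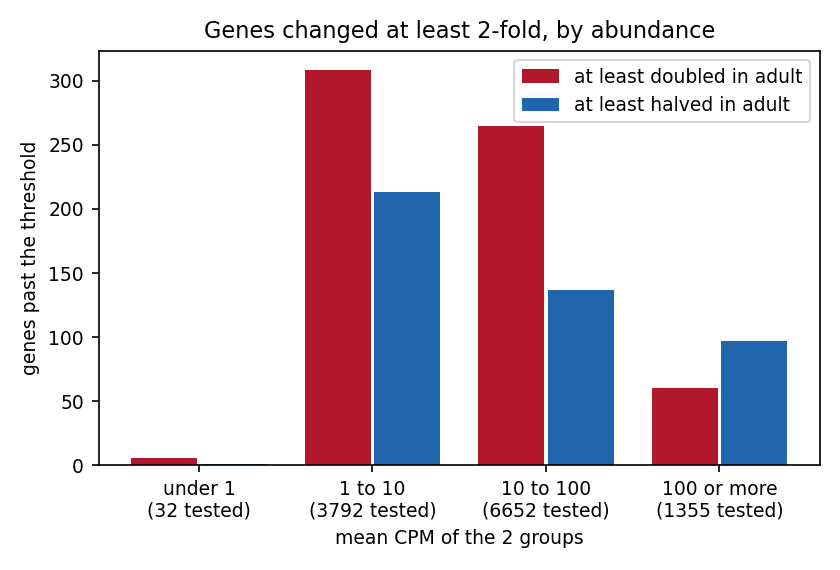
Number of genes at least doubled (red) or at least halved (blue) in the adult, by the mean CPM of both groups, with the number of genes tested under each class. In the counts shown, halved genes outnumber doubled ones only in the class of 100 CPM or more, 97 against 60. This order turned to 69 against 75 with scaling by library size alone, and differences between the classes were not tested.

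The 8 libraries separated by age. The first principal component held 57.9% of the variance and put the adult libraries between −38.7 and −31.2 and the foetal libraries between 32.7 and 37.3. Libraries of a group resembled each other more than those of the other group in the medians of Spearman's correlation across genes, which were 0.974 within the adults, 0.988 within the foetuses and 0.941 between the groups (genes are not independent replicates). The ranges overlapped in part, since the lowest adult pair reached 0.944 and the highest pair between the groups 0.954. The second component held 17.4% of the variance and spread the adult libraries, with scores of 33.6, 11.4, −1.50 and −42.4 for replicates 1 to 4, while the foetal libraries lay between −5.44 and 2.36. No library appeared to be a second deposit of another, since the lowest chi-square per degree of freedom of a pair was 12.0 in the adult and 7.70 in the foetus.

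**Figure D4:**
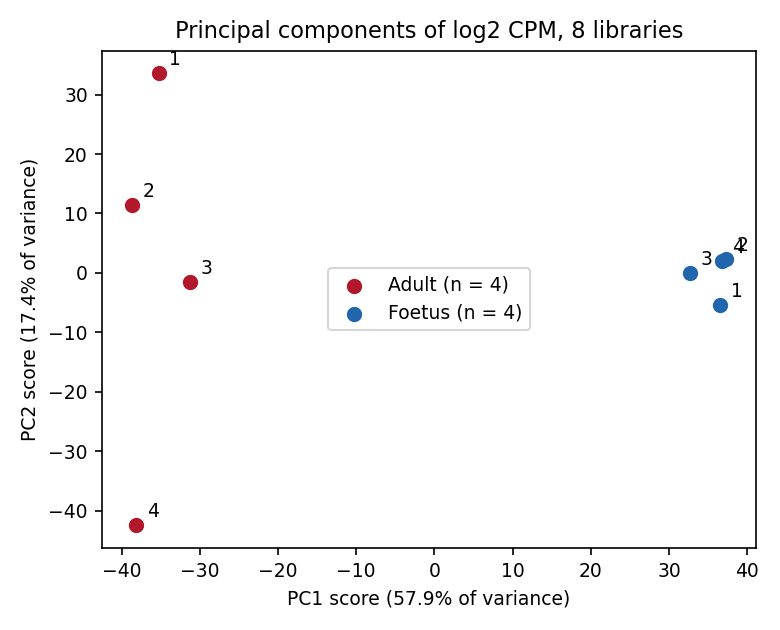
Scores of the 8 libraries on the first and second principal components of log2 CPM, which hold 57.9% and 17.4% of the variance. Numbers are replicates. Adult (red) and foetal (blue) libraries lie apart on the first component, and the adult libraries range from −42.4 to 33.6 on the second.

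Adult hearts differed more from each other than foetal hearts did, although not past the threshold. The root mean square SD between libraries was 0.38 on the log2 scale in the adult and 0.26 in the foetus (n = 4 each). The ratio of 1.48 had a permutation p of 0.0857, with a smallest possible p of 0.0286. The SD was larger in the adult for 8438 of the 11831 genes (71.3%). Adult replicate 4 contributed to this difference, and without it the ratio was 1.24 (permutation p = 0.0571). Without Adult replicate 1 the ratio fell too, to 1.38, while without Adult replicates 2 and 3 it rose to 1.56 and 1.61 (permutation p = 0.0571 each). Without Foetus replicates 1, 2, 3 and 4 it was 1.44, 1.41, 1.59 and 1.41 (permutation p = 0.257, 0.257, 0.0857 and 0.286). Leaving out a library changes the group sizes and the splits, so a lower p than with all 8 libraries is not firmer evidence.

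With all 8 libraries, none of 6 measures of library make-up passed the test between adult and foetus. The 10 most abundant genes of each library took 26.7% ± 3.09 of the counts in the adult and 25.4% ± 1.23 in the foetus (SD, n = 4 each, exact permutation p = 0.543, adjusted p = 0.651). The difference, adult minus foetus, was 1.34 percentage points with all libraries, and with 1 library left out it ran from −0.0524 without Adult replicate 4 to 2.38 without Adult replicate 3. With the largest gene of Adult replicate 4 left out, this difference was −0.569 (exact permutation p = 0.6, unadjusted). Genes at 1 CPM or more numbered 11855 ± 130 in the adult and 11729 ± 98.2 in the foetus (SD, n = 4 each, exact permutation p = 0.171, adjusted p = 0.514). This difference of 126 genes ran from 78 without Foetus replicate 1 to 190 without Adult replicate 2, where the groups no longer overlapped (exact permutation p = 0.0286, unadjusted, the smallest possible). Reads outside annotated features made up 28.3% ± 2.29 in the adult and 26.1% ± 2.49 in the foetus (SD, n = 4 each, exact permutation p = 0.286, adjusted p = 0.571). The difference of 2.17 percentage points ran from 1.06 without Adult replicate 4 (exact permutation p = 0.571, unadjusted) to 3.41 without Foetus replicate 3 (exact permutation p = 0.0571, unadjusted). The share of ambiguous reads, adult minus foetus, differed by −0.0157 percentage points (exact permutation p = 0.143, adjusted p = 0.514), which ran from −0.0235 without Adult replicate 1 (exact permutation p = 0.0286, unadjusted) to −0.0123 without Adult replicate 4. The effective number of genes and the share of reads with no unique position had exact permutation p of 0.771 and 0.457 (adjusted p = 0.771 and 0.651), and with 1 library left out their differences, −28.0 genes and −0.938 percentage points, ran from −92.4 (without Adult replicate 3) to 42.0 (without Adult replicate 4) and from −1.62 (without Foetus replicate 3) to −0.276 (without Adult replicate 1).

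In Adult replicate 4 the gene ENSCPOG00000017401, chosen after its values were seen, took 12.2% of all counts assigned to genes (95% Wilson interval 12.1% to 12.2%). It took 1.98% to 2.36% in the other adult libraries and 2.19% to 2.91% in the foetal ones. The means were 46198 ± 49465 CPM in the adult and 25313 ± 4522 CPM in the foetus (SD, n = 4 each), and the difference did not pass the test (log2 fold change 0.87, SE 0.52, adjusted p = 0.224 by edgeR). Without Adult replicate 4 the log2 fold change was −0.25, with an adjusted p of 0.179 by edgeR, within a range over its alternatives of 0.122 to 0.873.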

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

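The test of the position of Adult replicate 4 between the groups, the test of a factor that moved the same genes in Foetus replicate 3, and the alternatives that thinned the libraries or left out the most abundant gene of Adult replicate 4 were chosen only after the result was seen.

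Of 26 sets of 4 libraries checked for a library far from the rest, 2 had one, where chance alone would give about 1 in 20, or 1.3. In Foetus replicate 3, 29.8% of reads lay outside annotated features, against 24.6% to 25.2% in the other foetuses, a gap of 0.889 of the range. In Adult replicate 2, 11662 genes reached 1 CPM, against 11901 to 11949 in the other adults, a gap of 0.833 of the range. Outside these sets, ENSCPOG00000017401, chosen because of its value in Adult replicate 4, had 120306 CPM there, against 18191 to 23940 CPM in the other adults, a gap of 0.944 of the range.

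Adult replicate 4 stood apart from the other adults, with a mean distance to them 1.32 times their mean distance to each other. It had a single-library departure in 313 genes, against 73 to 162 in the other adults. The total of the adult group, 5.31% of genes, was near the 5% that chance gives. Adult replicate 1 also departed, lying at least 2-fold above the other adults in 166 genes and below them in 31, against 92 and 153 for Adult replicate 4. Lower depth is argued against, since the distance ratio was 1.29 after all libraries were thinned to 8009143 counts. Without ENSCPOG00000017401 the ratio was 1.32. Every tested gene has the same weight in this distance, so leaving out 1 could hardly move it. The part of this abundant gene is therefore not decided. Foetal tissue or a swapped label would have put Adult replicate 4 at 0.5 or more on the axis from the other adults (0) to the foetuses (1). It lay at 0.135, where each of the other adults set against the remaining ones lay at 0.136, 0.0288 and 0.132. A technical factor that moved the same genes in Foetus replicate 3 is argued against, as their deviations from the group means correlated at 0.0198 across genes, within −0.18 to 0.14 for all 16 pairs of an adult and a foetal library. The quality or handling of this library stays open, since 31.6% of its reads lay outside annotated features, against 26.4% to 27.8% in the other adults, and 30.5% were assigned to genes, against 36.5% to 38.8%, and so do the site of dissection and a difference between individual animals, although no biological explanation was tested because the labels do not divide the adults.

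The adult libraries differed from each other more than the foetal libraries did, by a ratio of 1.48 that missed the threshold. Unequal depth is argued against as the cause, since the ratio was 1.45 after thinning. Whether it comes from Adult replicate 4 alone cannot be told apart from a spread of the whole group, because the ratio of 1.24 without that library fell between the bounds set for this test. A wider range of ages or histories among adults than among foetuses of 1 gestational day, or relatedness among the foetuses, could also give such a ratio and stays open. Foetus replicates 1 and 2, whose descriptions share a starting number, had deviations that correlated at −0.21, against −0.46 to −0.27 for the other foetal pairs. Deviations of unrelated libraries from the mean of their group of 4 would correlate at about −0.33, so this pair was the highest and lay above that value. However, the distance of 0.333 between replicates 1 and 2 lay between the 0.331 of replicates 2 and 4 and the 0.340 of replicates 1 and 4.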

How the results depend on the processing

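The alternatives that left out the most abundant genes, thinned the libraries or weighted them by quality, all settings of the spread and of genes at 100 CPM or more, and each library left out of 5 measures of library make-up, were chosen only after the result was seen. Of 22 settings, 21 kept the counts of genes higher and lower in the adult within 1.5 times. An adjusted p under 0.01 gave 1265 higher and 1078 lower, by the construction of the threshold. Doubled and halved genes stayed within 1.5 times in 23 of 23 settings, at 429 to 764 and 327 to 532. No called gene changed sign in any setting that tested it. DESeq2 kept 98.5% of the calls and limma-voom 96.4%. Leaving out 1 library gave 1629 to 2566 higher, 1458 to 2279 lower, 604 to 689 doubled and 439 to 530 halved genes, and kept 75.2% to 94.9% of the calls. The 2566 higher and 2279 lower genes were those without Adult replicate 4, where 4845 genes were called against 4032 with all libraries. Leaving out any other library called fewer genes than with all libraries, 3097 to 3955. With the replicate block there were 1863 higher, 1605 lower, 590 doubled and 455 halved genes. Same-numbered adult and foetal libraries correlated at −0.18 to 0.06 in their deviations, and the highest of 16 such correlations, 0.14, joined different numbers. These correlations gave no sign of a pairing by number, although they cannot exclude one. The block ended the call of ENSCPOG00000003907 (adjusted p = 0.0754 by edgeR), and no other named gene lost its call in any setting. Summing Foetus replicates 1 and 2 gave 1730 higher and 1542 lower genes, and also ended the call of ENSCPOG00000003907 (adjusted p = 0.117 by edgeR). The spread ratio ran from 1.24 to 1.63, with permutation p of 0.0571 to 0.286. Leaving out 1 library moved the difference in genes at 1 CPM between 78 and 190 and that in ambiguous reads between −0.0235 and −0.0123 percentage points, and each passed an unadjusted 0.05 in 1 of 8 settings, without Adult replicate 2 and without Adult replicate 1. Alternatives that needed gene names, and shares outside the 10 most abundant genes, were not run. In the simulations, with 200 genes changed, 23.5% of 1.5-fold changes were recovered. Since 4032 genes were called in the data, the recovery of small changes there may differ and was not measured.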

Other observations

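The counts of splits, the share without Adult replicate 1 and the breakdown by abundance were chosen only after the result was seen.

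Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many higher, lower, doubled or halved genes. This is the smallest share that 35 splits can give. Each other split has both ages on each side, which adds the age difference to its residual spread. The calls in those splits therefore do not show how many genes chance would call, and no conclusion on chance is drawn. The real split called 4032 genes with edgeR and the highest of the other splits 0. At an unadjusted p under 0.05 the real split had 5290 genes and the others 70 to 1982.

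More genes were doubled than halved in the adult, with a share of 58.8% among those changed at least 2-fold. The tables argue against genes near the detection limit as its cause, since it was 58.1% among genes with a mean of at least 10 CPM, and against Adult replicate 4, since it was 56.7% without that library. Neither a part of Adult replicate 1 nor the choice of scaling can be told apart from a true excess, because the share without Adult replicate 1, 53.3%, and the lowest share under 3 other scalings, 54.5% with upper-quartile factors, fell between the bounds set for the tests, as did limma-voom with 54.6% and with quality weights 54.0%. The share was 57.9% with DESeq2 size factors and 66.4% with library size alone. A hypothesis left open is that the adult ventricle may gain more moderately expressed transcripts than it loses while some abundant foetal transcripts decline. It was not tested on other animals, and among genes at 100 CPM or more the order of halved against doubled genes turned with scaling by library size alone, to 69 against 75.

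Single-library departures were uneven in the foetal group too. Foetus replicate 3 departed from the other foetuses in 279 genes, against 120 to 146 for the others, although the group total of 5.63% of genes was near the 5% that chance gives. In the adult group the total was 5.31%.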
